A study of Mus musculus with 4 samples.

How the data were processed

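RNA of bone marrow-derived dendritic cells (BMDC) from C57BL/6 mice was measured on 4 Affymetrix mouse expression arrays, 1 array for each of 4 culture conditions. Per the labels, bone marrow was grown in medium with 500 U/ml GM-CSF, the cytokine that drives myeloid progenitors towards dendritic cells, for 7 days. Cells were then stained with a fluorescein-labelled antibody to CD80, a costimulatory surface protein, and sorted by flow cytometry before RNA extraction. RNA was amplified in 1 round from an oligo-dT primer carrying a T7 promoter and labelled with biotin. The deposited values are 1 signal per probe set, which the authors made with GCOS 1.4 and MAS5, the Affymetrix software that combines the perfect-match and mismatch probes of a set into 1 linear signal. The scaling target is not stated in the labels. On all 4 arrays the mean signal without the lowest and highest 2% of probe sets lay between 150.0 and 150.4, so the arrays had been scaled to a common level, and no further normalization was applied. MAS5 subtracts mismatch signal, which makes ratios of dim probe sets noisy, and a common trimmed mean forces genes that are lower to be balanced by genes that are higher. Detection calls were not used here.

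The table held 45101 probe sets, of which 64 were Affymetrix control probe sets and were left out of all counts. Of the others, 34945 were assigned to 1 gene, 932 to several genes, and 9160 were not in the annotation of the array. The 10092 probe sets without a single gene were left out of gene counts. Symbols were matched to the RefSeq genes of assembly GRCm38.p6 through Entrez gene identifiers for 34741 probe sets and none had to be replaced. This gave 18193 genes, 9010 of them with several probe sets. Each gene was represented by its probe set with the highest mean log2 signal over the 4 arrays.

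Signals below a floor of 44.3, the 50th percentile of all non-control signals pooled over the 4 arrays, were set to the floor. Ratios were then taken on the log2 scale. A gene was counted as higher or lower when the signals differed at least 2-fold after this step. Where the dimmer signal was at or under the floor, the ratio is a lower bound and is given as "at least". With 1 array per condition there were no replicates, no error could be computed for any value, and no test was run and no p-value is given for any gene. The words higher and lower therefore describe these 4 arrays only. Array data give no counts, and the number of arrays limits the precision. The closest measures of error in the data are the spread of log2 ratios between the 2 most similar arrays, the spread between probe sets of the same gene, and comparisons that share no array.

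The 38 gene lists cover signalling pathways, metabolism, stress responses, antigen presentation and markers of cell types that the cultures or the sort could have contained. For each list the median log2 ratio of its measured members was placed among the medians of 10000 random lists of the same size, drawn from 20 bins of mean log2 signal so that brightness matched. A list with at least 5 measured members was said to stand apart when its median lay below the 2.5th or above the 97.5th percentile of the random lists. This comparison assumes that genes vary independently of each other. Genes of a pathway do not, so a percentile is a description and not a significance level. The lists share some members.

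Genes named in the text are the 10 with the highest and the 10 with the lowest log2 ratio in each of the 3 comparisons with the control, the 5 highest and 5 lowest in each of the 3 comparisons between treated arrays, up to 4 members of each list with the largest ratios among those at least 2-fold apart, and every member of the list of study genes. Symbols of clone or model form, 1854 in all, were skipped in this ranking. Genes outside the rule are identified where they appear. The lists, the floor, the fold threshold, the naming rule and the alternatives were set before the data were examined.

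The alternatives were a floor at the 25th percentile (12.9) or the 75th percentile (155.6), quantile normalization, centring of each array on the median log2 signal of probe sets above the floor on all arrays, the mean over all probe sets of a gene, and a 3-fold threshold for the counts of the 6 comparisons. The steps were tested on simulated data for the comparison of live coculture with control, over 18193 genes, with the noise set to the spread between the coculture arrays. This noise was lower than in the comparison itself. The SD of a log2 ratio judged from 2 probe sets of the same gene was 0.19 between the cocultures and 0.41 for live coculture against control. The shares that follow hold for the lower noise, and may be too favourable for comparisons with the control. The altered genes were drawn from those well above the floor. Of 50 genes altered 2.5-fold, 98% were counted, as were 98% of those altered 4-fold and 8-fold and 10% of those altered 1.5-fold. Of unaltered genes, 0.868% were counted. A simulated list of 30 genes shifted by 0.5 on the log2 scale lay at percentile 100, and 2 of 100 unshifted lists stood apart. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.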

Results

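The series compared BMDC under 4 conditions, with 1 biological sample and 1 array for each. Control BMDC were cultured alone. For the live coculture, BMDC were cultured with 1D8 cells, a mouse ovarian surface epithelial line, at 1 tumour cell to 5 BMDC. For the irradiated coculture the 1D8 cells had received 50 Gy. For the conditioned medium sample, 25% (v/v) of the medium was 1D8 supernatant, so no tumour cell was present. All samples were sorted on CD80 before RNA extraction. The median signal was 38.7 on the control array, 46.8 on the live coculture array, 45.3 on the irradiated coculture array and 46.6 on the conditioned medium array, and 58.8% to 62.5% of the 18193 genes exceeded the floor. The ratio of the 3' to the 5' probe set of Actb, a measure of RNA integrity, was 1.30 in the control, 1.14 in the live coculture, 1.12 in the irradiated coculture and 1.20 in the conditioned medium. For Gapdh the same ratio was 0.880 in the control, 0.807 in the live coculture, 0.797 in the irradiated coculture and 0.793 in the conditioned medium.

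The title of the series concerns suppression induced through Toll-like receptor 3 (TLR3), with suppressor of cytokine signalling 3 (SOCS3) binding tyrosine kinase 2 (TYK2), a kinase of the type I interferon receptor. Of these genes, Socs3 differed most from the control. Its signal was 399.9 in the control, 953.9 in the live coculture (2.39-fold higher), 1486 in the irradiated coculture (3.72-fold higher) and 705.7 in the conditioned medium (1.76-fold higher, under the 2-fold threshold). Tlr3 had signals of 80.6, 79.8, 117.8 and 91.9 in the same order, and Tyk2 had 397.2, 457.8, 439.7 and 393.4. No difference between any pair of arrays reached 2-fold for Tlr3 or Tyk2. Stat2, a transcription factor of the interferon response, had signals of 153.4, 149.3 and 176.2 in the control and the cocultures and 456.8 in the conditioned medium (2.98-fold higher than the control). Another probe set of Stat2 had log2 ratios to the control of -1.22 in the live coculture, -0.83 in the irradiated coculture and 1.19 in the conditioned medium, so its 2 probe sets differ for both cocultures and no direction is given for them. The receptor subunits Ifnar1 and Ifnar2, the adaptor Ticam1, the kinase Tbk1 and the transcription factors Irf3, Irf9 and Stat3 differed by less than 2-fold from the control on all 3 treated arrays at their brightest probe sets, while another probe set of Ifnar1 had a log2 ratio of -1.11 in the live coculture. The signal of Socs1 was 75.8 in the irradiated coculture and under the floor on the other arrays. The brightest probe set of Jak1 was 1.15-fold lower in the live coculture than in the control, while another probe set of the gene differed by a log2 ratio of 1.64 in the opposite direction, so no direction is given for Jak1.

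The comparison of the live coculture with the control asked how the sorted sample differed after culture with tumour cells. The coculture sample may hold tumour cell RNA, since Krt19, a keratin, had a signal of 8.6 in the control and 569.7 in the coculture. A gene that differed may have done so in BMDC or may stem from tumour cells. No sample of 1D8 cells alone was analysed here to tell these apart. Chemokines that attract neutrophils and monocytes were among the genes with the largest differences. The signal of Cxcl1 was 62.7 in the control and 1293 in the coculture (20.6-fold higher). Cxcl2 was 15.8-fold higher, Cxcl3 15.3-fold higher and Ccl7 15.0-fold higher, and 10 of 34 measured chemokines were higher against 1 lower. The 1 was Ccl22, a chemokine of mature dendritic cells that attracts T cells, with a signal of 1417 in the control and 229.1 in the coculture (6.18-fold lower). Of 21 inflammatory cytokines, 7 were higher and 1 was lower. Il1a was 12.3-fold higher, Il1b 10.7-fold higher, and Il6 at least 8.25-fold higher, with a signal of 35.0 in the control and 365.3 in the coculture. The medians of both lists lay within those of random lists (0.00 at percentile 55.6 for chemokines and 0.02 at percentile 93.8 for cytokines), since most members were dim on every array or differed little.

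Hypoxia and glycolysis genes were higher as a group, with 16 of 30 members at least 2-fold higher, none lower, and a median log2 ratio of 1.08 (percentile 100). Egln3, a prolyl hydroxylase induced by hypoxia, was at least 23.8-fold higher. Bnip3, a mitophagy receptor, was 11.7-fold higher and Ero1a, an oxidase of the endoplasmic reticulum, was 5.51-fold higher. Hilpda, a lipid droplet protein induced by hypoxia, was 15.6-fold higher. Immediate early and stress genes were also higher, 13 of 29 with none lower and a median of 0.83 (percentile 100), among them Nr4a1 (8.61-fold), Nr4a2 (6.11-fold), Fosb (5.94-fold) and Myc (5.28-fold). Of 31 suppressive and regulatory molecules 6 were higher and none was lower (median 0.30, percentile 100). With the floor at the 75th percentile this median was 0.00 (percentile 58.4) and no longer stood apart. Arg1, which depletes arginine, was 19.0-fold higher with a signal of 8117. Ptgs2, the inducible cyclooxygenase of prostaglandin E2 synthesis, was 12.8-fold higher. Nt5e, the ectonucleotidase that makes adenosine, was at least 7.23-fold higher, and Vegfa was 3.76-fold higher. On the same array 8 of 32 epithelial and mesothelial markers were higher than in the control.

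Genes of antigen presentation were lower as groups on this array, on which epithelial markers were higher. For MHC class II presentation the median log2 ratio was -0.73 (percentile 0.01), with 3 of 14 members at least 2-fold lower and none higher. H2-Eb1 had a signal of 4244 in the control and 1348 in the coculture (3.15-fold lower), and H2-Ab1 was 2.03-fold lower, which became less than 2-fold after quantile normalization (log2 ratio -0.84). The 2 other probe sets of H2-Ab1 above the floor had log2 ratios of -1.57 and -1.71 as deposited. Ciita, the transactivator of MHC class II genes, was 3.68-fold lower at its brightest probe set. No other probe set of Ciita exceeded the floor on these 2 arrays, so its mean over probe sets (log2 ratio -0.63) was shrunk by construction. For MHC class I presentation the median was -0.48 (percentile 0.27), with 1 of 17 members lower and none higher. The list of dendritic cell maturation and costimulation had 5 of 25 members lower and 3 higher. Its median of -0.27 (percentile 1.18) no longer stood apart after quantile normalization (-0.11, percentile 34.7) or with the floor at the 75th percentile (0.00, percentile 56.1). Ccr7, the receptor that guides dendritic cells to lymph nodes, was 4.53-fold lower, and Tnfsf9, a costimulatory ligand, was 4.05-fold higher. Cd80, the gene of the surface protein used for the sort, was 4.42-fold higher and is not independent of the gate. Type I interferon response genes had a median of -0.39 (percentile 0), with 4 of 44 lower and none higher. With the floor at the 75th percentile this median was -0.059 (percentile 10.7) and no longer stood apart. The lower genes included Rsad2, an antiviral enzyme (2.65-fold lower, with a log2 ratio of -0.88 as the mean over its probe sets). Usp18, a negative regulator of interferon signalling, was 2.10-fold lower. Interferon gamma response genes had a median of -0.51 (percentile 0), with 2 of 19 lower and 1 higher.

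Markers of other cells also differed between these arrays. Of 32 epithelial and mesothelial markers, 8 were higher in the live coculture and none was lower (median 0.34, percentile 100). Krt19, a keratin, had a signal of 8.6 in the control and 569.7 in the coculture (at least 12.9-fold higher). Krt8 was 5.85-fold higher and Upk3b, a mesothelial uroplakin, was at least 5.35-fold higher. Of 56 matrix and mesenchymal markers 10 were higher and 1 was lower (median 0.18, percentile 100), with Cald1 5.56-fold higher and Sparc 4.58-fold higher at their brightest probe sets. The 2 other probe sets of Sparc above the floor disagreed, with log2 ratios of -0.03 and 3.18. Tm4sf1, a surface protein of epithelial and endothelial cells, was at least 17.8-fold higher at its brightest probe set, while another had a log2 ratio of 0.28. Of 19 neutrophil markers 8 were lower and 3 were higher (median -0.79, percentile 0). The granule genes Hp and Ctsg were 7.79-fold and at least 5.26-fold lower, while Mmp9 was at least 6.33-fold higher. With the higher floor the medians of the epithelial, matrix and neutrophil lists were 0.00 (percentiles 50, 50 and 51.8) and no longer stood apart. The mast cell and basophil proteases Cpa3 and Mcpt8 were 8.73-fold and at least 8.70-fold lower, the only 2 of 18 such markers that differed 2-fold. The fatty acid binding protein gene Fabp4 was the lowest of the ranked genes, 8.94-fold lower with a signal of 4012 in the control.

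In total 612 genes were higher and 406 were lower in the live coculture than in the control. The split was 479 higher and 482 lower after quantile normalization and 490 and 559 after median centring, so which direction held more genes depended on the scaling. The median log2 ratio of genes above the floor on all arrays was -0.04 as deposited and -0.16 after centring.

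**Figure D1:**
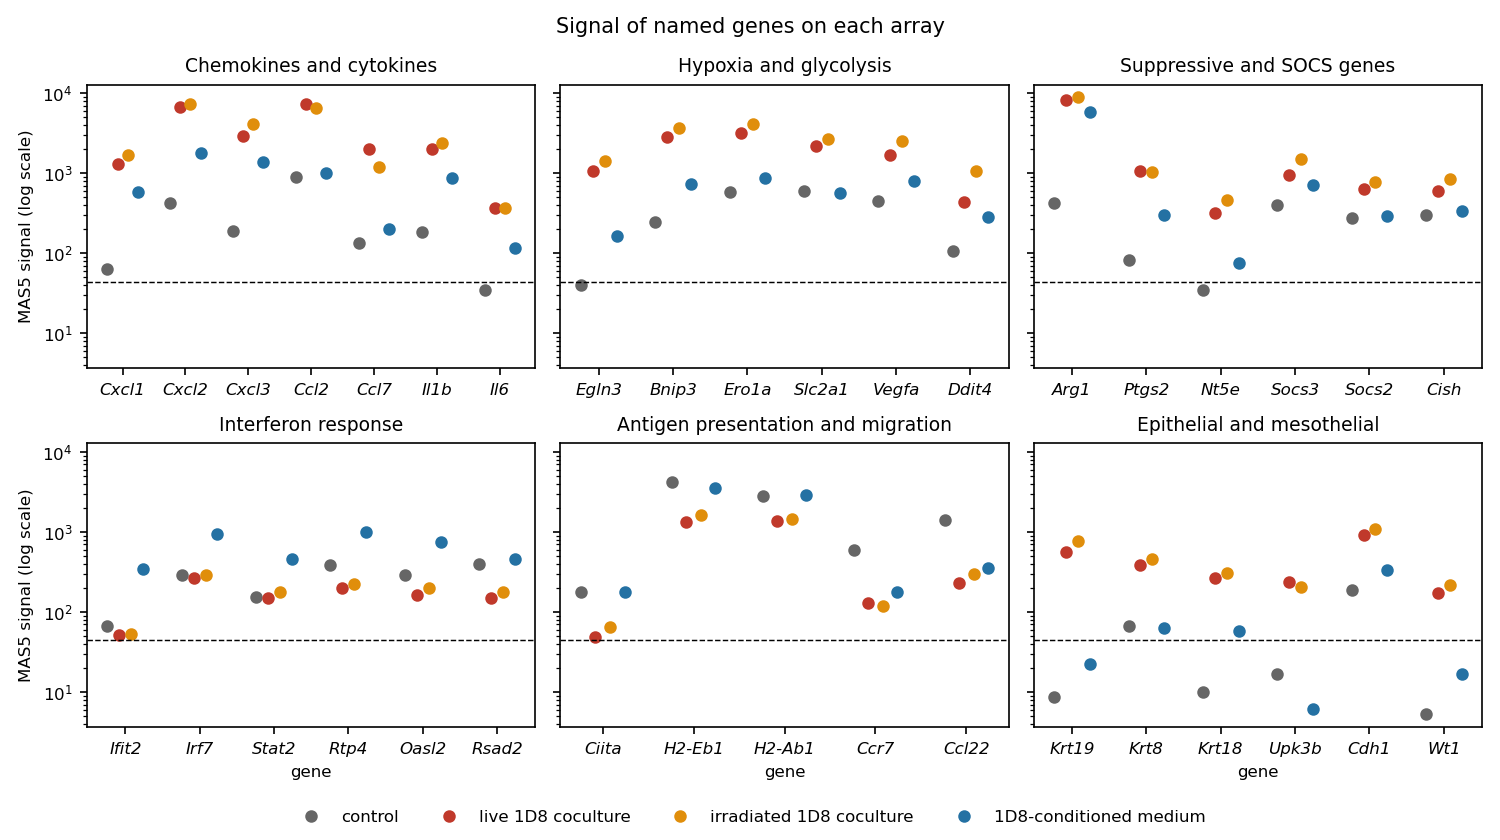
Each point is the MAS5 signal (log scale) of 1 named gene on 1 array, with 4 arrays per gene in grey (control), red (live coculture), orange (irradiated coculture) and blue (conditioned medium), and the dashed line is the floor of 44.3. Keratins such as Krt19 lie near or under the floor without tumour cells and at 569.7 and 767.4 in the cocultures, and interferon response genes such as Irf7 are highest in conditioned medium (941.6, against 287.3 in the control).

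The comparison of the irradiated coculture with the control asked the same for tumour cells that had received 50 Gy. The same limit holds on which cells a difference came from. The ranked genes again included chemokines, hypoxia genes and Arg1. Cxcl1 was 27.1-fold higher than in the control, Cxcl3 21.8-fold higher and Cxcl2 17.5-fold higher. Egln3 was at least 31.9-fold higher and Hilpda 16.9-fold higher. Arg1 was 20.7-fold higher with a signal of 8843. Hypoxia and glycolysis genes had a median log2 ratio of 1.29 (percentile 100), with 17 of 30 higher and none lower, and Ddit4, an inhibitor of mTOR complex 1 induced by hypoxia and stress, was 10.1-fold higher. Immediate early and stress genes had a median of 1.01 (percentile 100), with 15 of 29 higher and 2 lower. Fosb was 7.03-fold higher, Dusp1, a phosphatase of MAP kinases, was 5.42-fold higher and the small heat shock protein gene Hspb1 was 4.63-fold higher. On the same array 9 of 32 epithelial and mesothelial markers were higher.

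Of the 8 SOCS family genes 3 were higher and none was lower, with a median of 0.74 (percentile 99.95). These were Socs3, Cish, an inhibitor of STAT5 signalling (2.84-fold), and Socs2 (2.80-fold, with a log2 ratio of 0.80 as the mean over its probe sets). Inflammatory cytokines had a median of 0.35 (percentile 99.98), with 7 of 21 higher and 1 lower, and Il1b was 12.7-fold higher and Il6 at least 8.33-fold higher. Chemokines had a median of 0.14 (percentile 100), with 9 of 34 higher and 1 lower. With the floor at the 75th percentile neither cytokines (0.00, percentile 50) nor chemokines (0.00, percentile 50.1) stood apart. Suppressive and regulatory molecules had a median of 0.36 (percentile 100), with 7 of 31 higher and none lower. Ptgs2 was 12.6-fold higher, Nt5e at least 10.4-fold higher and Vegfa 5.52-fold higher. MHC class II genes had a median of -0.61 (percentile 0.02), with 2 of 14 lower and none higher, H2-Eb1 being 2.57-fold lower, and did not stand apart with the floor at the 75th percentile (-0.22, percentile 5.36). MHC class I presentation genes had a median of -0.40 (percentile 0.74), with 2 of 17 lower and none higher, and did not stand apart as the mean over probe sets (-0.26, percentile 3.77) or with that floor (-0.26, percentile 4.46). In the maturation list 6 of 25 members were higher and 5 lower, with a median of 0.02 within the random lists (percentile 73.1). Ccr7 was 5.08-fold lower and Ccl22 4.71-fold lower, while Tnfsf9 was 5.08-fold higher. Type I interferon response genes had a median of -0.22 (percentile 1.31), with 2 of 44 lower and none higher. With the floor at the 75th percentile neither the live coculture (-0.059, percentile 10.7) nor the irradiated coculture (0.00, percentile 66.2) stood apart for this list. The median of interferon gamma response genes, -0.14, lay within the random lists (percentile 8.67).

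Epithelial and mesothelial markers had a median of 0.58 (percentile 100), with 9 of 32 higher and none lower. The signal of Krt19 was 767.4 (at least 17.3-fold higher), that of Krt8 was 458.0 (6.93-fold higher) and that of Cdh1, the epithelial cadherin gene, was 1102 against 189.5 in the control (5.82-fold higher). Matrix and mesenchymal markers had 12 of 56 higher and 1 lower with a median of 0.04 (percentile 99.7), which was 0.00 after quantile normalization (percentile 53.2), and Sparc was 6.52-fold higher at its brightest probe set. The 2 other probe sets of Sparc above the floor had log2 ratios of -0.35 and 3.23. Neutrophil markers had 7 of 19 lower and 3 higher with a median of -0.35 (percentile 0.105), which no longer stood apart after quantile normalization (-0.25, percentile 3.38). With the higher floor the medians of these 3 lists were 0.00 (percentiles 50, 50 and 51.7) and none stood apart. In total 632 genes were higher and 409 lower in the irradiated coculture than in the control, 530 and 468 after quantile normalization and 558 and 504 after median centring. The median log2 ratio of genes above the floor was -0.05 as deposited and -0.12 after centring.

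The comparison of conditioned medium with the control asked how BMDC differed when exposed to what the tumour cells had released, without tumour cells. Type I interferon response genes were higher, 12 of 44 at least 2-fold with none lower, and 40 of 44 had a ratio above 0 (median 0.59, percentile 100). Ifit2, an antiviral protein gene, had a signal of 66.2 in the control and 345.3 in conditioned medium (5.22-fold higher). Ddx60, a helicase that promotes RNA sensing, was 3.69-fold higher. No other probe set of Ddx60 exceeded the floor on these 2 arrays, so its mean over probe sets (log2 ratio 0.94) was shrunk by construction. Irf7, the transcription factor that amplifies interferon production, was 3.28-fold higher, and Stat2 was 2.98-fold higher. Of the 9 measured genes that encode type I and III interferons, none was 2-fold apart from the control on any of the treated arrays, and at most 3 exceeded the floor in any of these comparisons.

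Arg1 was 13.7-fold higher in conditioned medium than in the control and had the largest ratio of the ranked genes. Cxcl1 was 9.19-fold higher, Cxcl3 7.23-fold higher and Slfn4, a schlafen gene of myeloid cells, 5.78-fold higher. Inflammatory cytokines had a median of 0.22 (percentile 99.6), with 4 of 21 higher and none lower, including Il1b (4.73-fold), but did not stand apart with the floor at the 75th percentile (0.00, percentile 50). Suppressive and regulatory molecules had a median of 0.00 (percentile 66.7), with 2 of 31 higher, Arg1 and Ptgs2 (3.71-fold). Hypoxia and glycolysis genes had a median of 0.15 (percentile 99.5) with 5 of 30 higher and none lower. Egln3 was at least 3.67-fold higher at its brightest probe set, while another had a log2 ratio of 0.41. Immediate early and stress genes had a median of 0.04 (percentile 86.8) with 1 of 29 higher and 4 lower. Of 34 chemokines 5 were higher and 2 lower, with a median of 0.00 (percentile 52.4). Cell cycle genes were higher, 10 of 42 with none lower and a median of 0.69 (percentile 100), among them Tk1, the S-phase thymidine kinase gene (3.85-fold), and Kif11, a spindle kinesin gene (2.80-fold).

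MHC class II and class I presentation genes had medians of -0.01 (percentile 70.7) and -0.05 (percentile 56.8), both within the random lists, with 0 of 14 and 1 of 17 members lower. The maturation list had a median of -0.23 (percentile 1.07), with 3 of 25 members lower and 2 higher, and did not stand apart after quantile normalization (-0.15, percentile 13.7) or with the higher floor (0.00, percentile 52.3). Ccl22 was 3.98-fold lower, Ccr7 3.39-fold lower and Ccl17, a related T cell chemokine, 2.94-fold lower. None of the 32 epithelial and mesothelial markers was 2-fold apart from the control (median 0.00, percentile 47.2), and 1 of 56 matrix markers was higher and 2 were lower (median 0.00, percentile 48.5). The SOCS family had a median of 0.04 (percentile 63.7) with 0 of 8 members 2-fold apart. Neutrophil markers had 5 of 19 lower and 2 higher, with a median of 0.00 (percentile 42.2). S100a9, a calgranulin gene, was at least 4.84-fold lower and Padi4, a peptidylarginine deiminase gene, was 5.40-fold higher. In total 419 genes were higher and 256 lower, a split that was 284 and 339 after quantile normalization and 300 and 408 after median centring. The median log2 ratio of genes above the floor was 0.00 as deposited and -0.11 after centring.

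**Figure D2:**
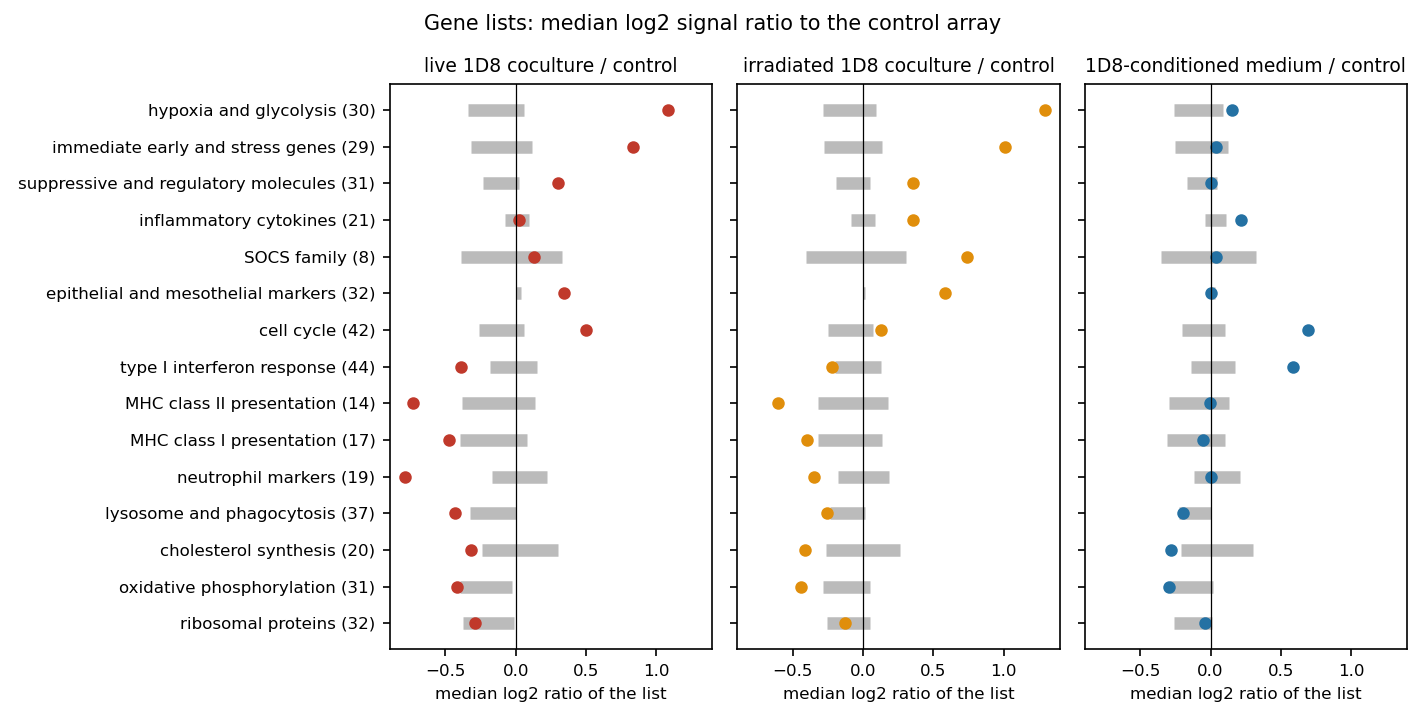
Each point is the median log2 ratio of the measured members of 1 gene list (number of members in brackets) to the control array, for the live coculture (left), the irradiated coculture (middle) and conditioned medium (right), and each grey bar spans the central 95% of medians of 10000 random lists matched for signal. Hypoxia and glycolysis lies at 1.08, 1.29 and 0.15, type I interferon response at -0.39, -0.22 and 0.59, and MHC class II presentation at -0.73, -0.61 and -0.01.

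Live and irradiated cocultures were compared to ask what irradiation of the tumour cells altered. These were the most similar arrays, with 67 genes higher and 55 lower in the live coculture. These genes were 0.67% of all, while the simulation counted 0.868% of unaltered genes at noise set to the spread between these arrays. By count alone, the genes named here cannot be told apart from noise. The split turned with the scaling, to 51 higher and 59 lower after quantile normalization and 44 and 66 after median centring. The log2 signals of genes above the floor correlated across genes at r = 0.98. Genes are not independent replicates, and no sample was repeated. Both samples may hold tumour cell RNA, so a difference may lie in BMDC or in tumour cells, which were not told apart. Cell cycle genes were higher in the live coculture, with a median log2 ratio of 0.41 (percentile 100) and 39 of 42 members above 0, although none reached 2-fold. In the unfolded protein and integrated stress response list 3 of 27 members were higher and 1 was lower, with a median of 0.07 within the random lists (percentile 95.4). Asns, the asparagine synthetase gene, was 3.12-fold higher, Slc7a5, an amino acid transporter gene, at least 3.08-fold higher and Phgdh, a serine synthesis gene, 2.01-fold higher. Ddit4 was 2.46-fold lower. Lower medians in the live coculture were found for the SOCS family (-0.36, percentile 0.01), the interferon gamma response (-0.26, percentile 0.01), the type I interferon response (-0.19, percentile 0) and hypoxia and glycolysis (-0.17, percentile 0.20), with at most 1 member of each list 2-fold apart. The epithelial and mesothelial markers had a median of 0.00 (percentile 49.1) with 1 of 32 lower, Epcam (2.23-fold). Ch25h, the cholesterol 25-hydroxylase gene, was 3.27-fold higher and Rasgef1b 5.27-fold higher in the live coculture. The spread of log2 ratios between these arrays, as a robust SD, was 0.26, against 0.49 between live coculture and control. The SD of a log2 ratio judged from 2 probe sets of the same gene was 0.19 and 0.41. For the irradiated coculture and conditioned medium against the control this SD was 0.38 and 0.36. For the live and irradiated cocultures against conditioned medium it was 0.21 and 0.21. Probe sets of the same gene thus disagreed more in every comparison that used the control array, and ratios to the control are less precise.

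Coculture and conditioned medium were compared to ask how culture with tumour cells differed from culture with their supernatant. Contact is not isolated by this comparison. Supernatant was only a part of the conditioned medium, while the cocultures held the tumour cells themselves, whose RNA may be in the samples. The differences listed here may thus stem from contact, from the amount of soluble products or from tumour cell RNA, which were not told apart. In the live coculture 319 genes were higher and 207 lower than in conditioned medium, and in the irradiated coculture 354 were higher and 225 lower. Hypoxia and glycolysis genes were higher in both cocultures, with medians of 0.89 (live, percentile 100, 14 of 30 higher and 1 lower) and 1.11 (irradiated, percentile 100, 16 of 30 higher and 1 lower). Slc2a1, the glucose transporter gene, was 3.89-fold and 4.68-fold higher. Immediate early and stress genes had medians of 0.85 and 0.97 (percentile 100 in each), with 12 and 14 of 29 higher and none lower. Trib1, a pseudokinase gene, was at least 18.8-fold and at least 19.1-fold higher at its brightest probe set, while another had log2 ratios of 0.14 and 0.32. Trem1, a receptor that amplifies inflammation, was 12.6-fold higher in the live coculture. Ccl2, the monocyte chemokine gene, was 7.19-fold and 6.43-fold higher. Type I interferon response genes were lower in the cocultures, 21 of 44 (live, median -0.94, percentile 0) and 15 of 44 (irradiated, median -0.81, percentile 0) with none higher. Ifit2 was 6.65-fold and 6.41-fold lower and Rtp4, a chaperone gene induced by interferon, was 5.06-fold and 4.53-fold lower. MHC class II genes had medians of -0.64 and -0.53 (percentile 0 in each), with 5 of 14 lower in each and none higher. H2-Eb1 was 2.62-fold and 2.13-fold lower. Cell cycle genes had a median of -0.12 in the live coculture (percentile 6.16) and -0.49 in the irradiated coculture (percentile 0) relative to conditioned medium. Epithelial and mesothelial markers had 9 of 32 higher in the live coculture (median 0.21, percentile 100) and 8 of 32 in the irradiated coculture (median 0.40, percentile 100). Krt19 was at least 12.9-fold and at least 17.3-fold higher.

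The control stood apart from the 3 other arrays in 245 genes, in which it was at least 2-fold higher (105 genes) or lower (140 genes) than on every other array. The split was 118 higher and 105 lower after quantile normalization and 158 and 108 after median centring, so its direction depended on the scaling. The same number was 16 for the live coculture, 20 for the irradiated coculture and 46 for conditioned medium. In 28 of these 46 genes conditioned medium was highest, and 10 of the 28 belonged to the type I interferon response list. The control array also had the lowest median signal and the highest 3' to 5' ratios of Actb and Gapdh. Genes in which it stood apart may reflect that sample or the treatments, which 1 array cannot tell apart. Ratios to the control share 1 array, so the overlap of such lists was not used. Pairs of comparisons that share no array were used in its place, a choice made after the data were seen. The number that independent lists would share was taken over the genes bright enough to be counted in both comparisons, with a signal of at least 2 times the floor on 1 array of each (8760, 8776 and 8587 genes in the 3 pairs). Of 612 genes higher in the live coculture than in the control, 215 were also higher in the irradiated coculture than in conditioned medium, where independent lists would share 20.2, and 71 of 406 lower genes were lower in both, against 7.07. For the irradiated coculture against the control and the live coculture against conditioned medium, 199 genes were higher in both, against 18.6, and 58 were lower in both, against 6.41. Across genes the log2 ratios of these pairs correlated at r = 0.42 in each case. For conditioned medium against the control and live against irradiated coculture r was 0.00, with 8 genes higher in both, against 1.79, and 4 lower in both, against 0.847. The last pair also exceeded these numbers, so an excess alone does not show a shared response.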

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

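All tests of explanations given here were chosen after the results were seen, while quantile normalization of list medians was an alternative set before. The type I interferon response list differed from the control in opposite directions in conditioned medium and in the cocultures. The median log2 ratio in conditioned medium was larger by 0.98 and 0.81 than in the live and irradiated cocultures. With 1 array per condition this difference was not tested. With the floor at the 75th percentile the coculture medians (-0.059 and 0.00, percentiles 10.7 and 66.2) no longer stood apart, so the opposite direction rests on the floor chosen. After quantile normalization the list had a median of 0.55 in conditioned medium, at percentile 100 of random lists, so this result was kept under another scaling. The percentile is no test of scaling as a cause, since a shift of a whole array would move the random lists alike. A larger share of plasmacytoid dendritic cells cannot be told apart from a response of the cultured cells. Such cells make much type I interferon, and the sort would remove those without CD80. Bst2 (signals of 512.8 and 730.1 in control and conditioned medium) was left out because it is also an interferon response gene. The 6 other markers above the floor had a median log2 ratio of 0.053 (95% bootstrap interval -0.05 to 0.17). That bootstrap resampled the 6 genes and holds no error between cultures. The brightest of the 6, Tcf4, had signals of 284.1 and 288.5. Of the 6, 3 exceeded double the floor, under a minimum of 5 set after these values were seen. Variation between cultures cannot be told apart from an effect of the medium either, with 1 array per condition, and a response to what 1D8 cells release remains among the open explanations as a hypothesis.

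Probe sets without a single gene name formed no part of the gene counts, and many differed from the control. Of 10092 such probe sets, 213 were at least 2-fold higher in the live coculture, 195 in the irradiated coculture and 127 in conditioned medium, and 117, 93 and 51 were lower. What they measure is not analysed here.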

How the results depend on the processing

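Leaving out a replicate was not possible with 1 array per condition, and the alternatives were run for the counts of genes, the gene list medians and the ratios of named genes, the 3-fold threshold only for the counts of the 6 comparisons between arrays. They were not run for the overlaps and correlations of comparisons that share no array, the spreads between arrays or the probe sets without a single gene name. Of the counts of genes, 39 values under the alternatives lay within 1.5 times the reported count and 53 did not. Of the gene list medians that answer a comparison with the control and stood apart from random lists, 194 values kept their side of the threshold and their direction and 36 no longer stood apart. None reversed. Of the ratios of named genes, 2553 values were on the same side of 2-fold, 265 were no longer past it (153 with the higher floor, 88 with the mean over probe sets, 13 with quantile normalization and 11 with median centring) and 2 newly passed it. For the other lists and comparisons, 829 values kept their side, 52 newly stood apart and 29 no longer did.

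Signal over background set the counts. In the order higher then lower, a floor at the 25th percentile gave 1463 and 782 genes for the live coculture against the control, 1396 and 817 for the irradiated coculture, 1088 and 597 for conditioned medium, 573 and 490 for live against irradiated coculture, 894 and 677 for live coculture against conditioned medium, and 886 and 740 for irradiated coculture against conditioned medium. In the same order a floor at the 75th percentile gave 270 and 243, 293 and 232, 170 and 137, 12 and 13, 153 and 88, and 176 and 87. By construction a lower floor admits the noisier ratios of dim genes and a higher floor shrinks them. Genes in which 1 array stood apart from the 3 others numbered 529 for the control, 221 for the live coculture, 200 for the irradiated coculture and 226 for conditioned medium with the lower floor, and 128, 8, 6 and 18 with the higher floor. At a 3-fold threshold the counts were 194 and 77, 230 and 96, 61 and 37, 8 and 4, 104 and 37, and 125 and 35, fewer by construction.

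The mean over probe sets gave 251 genes lower in the live coculture than in the control, 263 in the irradiated coculture and 145 in conditioned medium, 31 higher and 30 lower in live against irradiated coculture, and 12 and 29 genes in which the irradiated coculture and conditioned medium stood apart. Median centring gave 408 genes lower in conditioned medium than in the control and 44 higher in live than in irradiated coculture. By construction, the mean takes in probe sets under the floor, which shrink ratios. Centring shifts all ratios above the floor in a comparison alike. How much of these changes this accounts for was not tested.

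With the higher floor the following medians against the control no longer stood apart. A median of 0.00 was found in the live coculture for maturation and costimulation, suppressive molecules, unfolded protein and integrated stress response, p53 targets, neutrophil markers, epithelial markers and matrix markers. The same value, 0.00, was found in the irradiated coculture for type I interferon response, inflammatory cytokines, chemokines, neutrophil markers, epithelial markers and matrix markers, and in conditioned medium for maturation and costimulation, inflammatory cytokines and B cell markers. By construction members under the floor on both arrays have a ratio of 0. In the live coculture type I interferon response had -0.059, and in the irradiated coculture MHC class II had -0.22, MHC class I -0.26 and lysosome and phagocytosis -0.21. With the lower floor p53 targets in conditioned medium had 0.21 (percentile 97.4).

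After quantile normalization maturation and costimulation had -0.11 in the live coculture and -0.15 in conditioned medium, oxidative phosphorylation had -0.22 in the live coculture, neutrophil markers -0.25 and matrix markers 0.00 in the irradiated coculture, and alternative macrophage activation 0.00 and p53 targets 0.13 in conditioned medium. After median centring alternative macrophage activation had 0.00 in the live coculture and 0.00 in conditioned medium. With the mean over probe sets it had 0.012 in the live coculture and 0.00 in conditioned medium, MHC class I had -0.26 and lysosome and phagocytosis -0.23 in the irradiated coculture, unfolded protein and integrated stress response 0.13 in the live coculture and p53 targets 0.17 in conditioned medium. For these settings the cause was not tested.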

Other observations

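Other gene groups, each compared with the control, were not yet described. Ratios on the 3 treated arrays share the control array, so agreement among them is not independent and could stem from that array. Cell cycle genes were higher in the live coculture, 9 of 42 with none lower and a median log2 ratio of 0.50 (percentile 100), and had a median of 0.13 in the irradiated coculture (percentile 99.5) with 1 member higher. On these arrays 8 and 9 of 32 epithelial and mesothelial markers were also higher. Tk1 had signals of 180.1 in the control, 554.5 in the live coculture, 333.4 in the irradiated coculture and 694.0 in conditioned medium. Genes of cholesterol synthesis had medians of -0.32, -0.42 and -0.28 (percentiles 0.59, 0.08 and 0.58) and 4, 6 and 3 of 20 members lower and none higher in live coculture, irradiated coculture and conditioned medium. Without the control array, their median was -0.34 in the irradiated coculture relative to conditioned medium (percentile 0.20, with 0 of 20 members 2-fold apart) and -0.19 in the live coculture (percentile 3.94, within the random lists). Hmgcs1, which makes the precursor of mevalonate, was 2.89-fold, 2.96-fold and 2.23-fold lower at its brightest probe set, with log2 ratios of -0.84, -0.92 and -0.68 as the mean over probe sets. Oxidative phosphorylation genes had medians of -0.42, -0.44 and -0.29 (percentiles 1.35, 0.03 and 2.13), with no member 2-fold apart except Cox7c, 2.03-fold higher in the irradiated coculture. The first of these medians did not stand apart after quantile normalization (-0.22, percentile 3.10). Lysosome and phagocytosis genes had medians of -0.43, -0.26 and -0.20 (percentiles 0.03, 1.25 and 5.49), with 5, 6 and 2 of 37 lower and 1 higher each time. The second did not stand apart as the mean over probe sets (-0.23, percentile 2.80) or with the floor at the 75th percentile (-0.21, percentile 4.44). Mfge8, which bridges phagocytes to apoptotic cells, was 3.50-fold, 4.25-fold and 3.71-fold lower. The unfolded protein and integrated stress response list had 7 of 27 members higher in the live coculture (median 0.29, percentile 99.9), 5 higher and 1 lower in the irradiated coculture (-0.17, percentile 19.2) and 2 higher and 2 lower in conditioned medium (-0.12, percentile 24.3). The live coculture did not stand apart as the mean over probe sets (0.13, percentile 93.6) or with that higher floor (0.00, percentile 78.6). The p53 targets had medians of 0.28, 0.27 and 0.21 (percentiles 99.6, 99.7 and 99.0), with 4, 5 and 2 of 22 members higher and 1, 1 and 2 lower. In conditioned medium they did not stand apart after quantile normalization (0.13, percentile 97.4) or as the mean over probe sets (0.17, percentile 95.7), nor in the live coculture with the higher floor (0.00, percentile 66.7). The largest ratio among them in the cocultures was that of Ddit4, which hypoxia also induces and which the hypoxia and stress response lists hold too.

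Among other myeloid groups, alternative macrophage activation had medians of 0.01, 0.13 and 0.01 (percentiles 98.8, 99.6 and 97.6), with 5, 7 and 2 of 21 members higher and 1 lower each time. The live coculture no longer stood apart after median centring (percentile 90.2) or as the mean over probe sets (percentile 96.4). Conditioned medium no longer did after quantile normalization (percentile 52.97), after centring (percentile 87.7) or as that mean (percentile 60.6). F13a1, the coagulation factor XIII A gene, was 4.65-fold, 5.64-fold and 2.57-fold higher. Fc and complement receptors had medians within the random lists (-0.25, -0.03 and -0.03, percentiles 36.7, 73.6 and 81.7), with 3, 3 and 2 of 15 higher and none lower. Itgam, the CD11b gene, was 2.74-fold, 3.54-fold and 2.64-fold higher. Toll-like receptors and adaptors had 3, 3 and 2 of 22 members higher and 1, 2 and 0 lower, with medians of -0.02, 0.13 and -0.04 (percentiles 48.3, 94.9 and 30.2). Cd180, which restrains Toll-like receptor 4 signalling, was 3.11-fold and 4.01-fold lower in live and irradiated coculture, and Tlr4 was 2.25-fold and 2.33-fold higher. The 2 other probe sets of Tlr4 above the floor had log2 ratios of 0.86 and 1.77 in the live coculture. In the irradiated coculture they had 0.85 and 1.78. The mean over all Tlr4 probe sets, including any under the floor, was 0.95 and 0.96. Dendritic cell identity genes had 5, 5 and 3 of 23 lower and 0, 1 and 0 higher, with medians of -0.07, -0.06 and 0.00 (percentiles 19.8, 16.8 and 56.4). Macrophage markers had medians of -0.27, -0.13 and 0.00 (percentiles 20.4, 33.5 and 87.8). NF-kappaB targets had 4, 3 and 1 of 24 higher and 3, 4 and 0 lower, with medians of -0.24, -0.17 and -0.01. NRF2 targets had 5, 6 and 1 of 18 higher and 1, 0 and 0 lower, with medians of -0.02, 0.04 and 0.01. B cell markers stood apart in conditioned medium with a median of -0.12 (percentile 0.23), with no member 2-fold lower, but not with the floor at the 75th percentile (0.00, percentile 50). Chemokine receptors, apoptosis regulators and markers of mast cells and basophils, eosinophils, T and NK cells, erythroid cells and plasmacytoid dendritic cells had medians within the random lists on the 3 treated arrays. Ribosomal protein genes had no member 2-fold apart, with medians of -0.29, -0.13 and -0.04 within the random lists, and the last of these was 0.02 after quantile normalization.

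The tests of explanations given here, too, were chosen after the results were seen, while quantile normalization of list medians was an alternative set before. Epithelial and mesothelial markers were higher in both cocultures, and 7 of 32 were at least 2-fold higher in each. These were Cdh1, Krt8, Krt18, Krt19, Upk3b, Wt1 and Tjp1, of which Tjp1 was named after its values were seen. The list median was nevertheless 0.00 in both cocultures with the floor at the 75th percentile (percentile 50). A soluble factor acting at the strength of the conditioned medium is argued against, since 0 of the 7 were 2-fold higher in conditioned medium, with a median log2 ratio of 0.00 and a range from -0.32 to 0.83. After quantile normalization 7 stayed 2-fold higher in both cocultures, so the count was kept under another scaling. Tumour cell RNA carried through the sort, which would remove cells without CD80, may account for them. Krt19 had signals of 569.7 and 767.4 in the live and irradiated cocultures and 8.6 in the control. The highest signal, 1102 in the irradiated coculture, was that of Cdh1, which had 189.5 in the control and so says less about tumour cell RNA. In the control 7 of the 32 markers exceeded the floor, which does not show that BMDC express them. Expression induced in BMDC by contact remains open, because a sample of 1D8 cells alone was not analysed here.

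MHC class II genes were lower in both cocultures, but with the floor at the 75th percentile the median of the irradiated coculture (-0.22, percentile 5.36) did not stand apart. The medians after quantile normalization were -0.62 and -0.53 (percentiles 0 and 0.02), so the result was kept under another scaling. These percentiles are no test of scaling as a cause, since a shift of a whole array would move the random lists alike. Dilution of BMDC RNA by tumour RNA would lower Fc and complement receptor genes of the same cells alike. Their median exceeded that of the MHC class II list by 0.48 in the live coculture (95% bootstrap interval 0.03 to 1.14). In the irradiated coculture it did so by 0.57 (0.06 to 1.34). The bootstrap resampled the genes of each list, which are not independent, so the intervals hold no error between cultures. Since 2 of these 15 receptor genes, Itgam and Fcgr4, were also at least 2-fold higher in conditioned medium without tumour cells, they are no fixed reference, and dilution cannot be told apart from a response of BMDC to tumour cells. Both stay open, as does a difference between single cultures.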
